A study of Mus musculus with 244 samples.

How the data were processed

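Single cells were captured on a Fluidigm C1 chip, cDNA was made with the SMARTer Ultra Low RNA kit and libraries with Nextera XT, per the labels' protocols. The protocol text speaks of islet cells, whereas all other labels say macrophages of the aortic arch. The authors deposited 1 table of RPKM values (reads scaled by transcript length and by library size) for 24475 genes and 244 libraries. The mm10 genome build, CASAVA 1.8.2 and FastQC are named in the submitters' processing notes; the aligner, the annotation and the program that made the RPKM values are not given in the sources used here. The table lists 8840 genes at 0 in all cells, 22 rows that are not on a mouse chromosome (such as Neo and LacZ) and 37 mitochondrial genes. Of the values above 0, 0.90% lie under 0.001, below what a whole read could give, so these values were not all made from whole reads. SMARTer libraries carry no molecular identifiers, so amplification noise is part of each value, and genes that share reads with near-identical copies may be split in ways that cannot be seen in the table.

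Each column was matched to its sample by the number in the sample's title. Libraries whose log2 values correlated above 0.9 were treated as 1 library deposited more than once: 3 baseline pairs were averaged. Cells with at least 1000 genes at RPKM of 1 or more were kept, which left 125 of 125 baseline and 113 of 116 regression cells. Depth was estimated from genes with 1 annotated transcript (5624 in GENCODE vM21), as the step of which low values came closest to whole multiples by a score. In the median library, 61.0% of low values lay within 0.1 reads of a whole number of reads. Depth is given only for the 182 of 244 libraries in which 2 separate sets of genes gave the same step within 10%. In these it ran from 0.41 to 8.11 M reads at baseline and from 0.39 to 9.73 M reads in regression. Gene positions were taken from the same annotation, on the build that the processing notes name, for 23382 gene symbols that matched.

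Values were compared as log2(RPKM + 1). A difference is the mean over regression cells minus the mean over baseline cells. It is on the log2(value + pseudocount) scale, which understates the difference of low genes. RPKM values are not counts, so no count model was used. Each library is 1 cell and the labels name no animal, so each group is 1 sample: no test, standard error or count of genes past a threshold was made from cells. Shares of cells have exact (Clopper-Pearson) 95% binomial intervals, and a count of 0 is given with the share that 3 cells would make; both cover counting error only. Doublets were not called, since no caller fits RPKM values; cells with markers of other types are counted in the report. Over genes at RPKM of 1 or more in at least 25% of the cells of a group (3946 genes), the median difference was -0.05, and -0.11 after rescaling each cell to a sum of 1000000.

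The genes named were set by a rule fixed before the data were examined. Among genes listed at RPKM of 1 or more in at least 25% of the cells of a group, it takes the 12 with the highest and the 12 with the lowest difference whose log2 ratio of mean RPKM has the same sign. It leaves out predicted and clone-named genes, immunoglobulin and T-cell receptor segments, Rn45s, Xist and genes of the Y chromosome. It adds the 2 members of each list with the largest absolute difference, and 11 genes fixed by name. Other members of a list are named as examples, chosen after their values were seen. The 20 programme lists and 16 cell type lists held 372 symbols, of which 366 were in the table. List members had to be listed in at least 5% of the cells of a group. A list's median was placed among 10000 random lists of the same size, drawn from 20 bins of mean level. Mast cell, smooth muscle, fibroblast and adipocyte lists had no member past this filter. Some lists share genes, such as Mmp12 in the lipid-laden and protease lists and Npc1 and Npc2 in the efflux and lysosome lists.

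The method was tested on a simulated table of 24475 genes, in which 200 genes were changed by 1 or 2 on the log2 scale. Of these, 192 had the right sign. The changed genes were drawn from genes listed in many cells, not from all genes of the table. True changes of 1 and 2 came out with medians of 0.73 and 1.56, and those of -1 and -2 with medians of -0.58 and -1.17. The share of right signs and these medians therefore do not cover genes listed in few cells, for which recovery was not tested. Of 200 simulated lists of 14 unchanged genes, 11 lay outside the central 95% of random lists, and 200 of 200 moved lists lay above percentile 97.5. The simulated lists were themselves drawn at random, and every member of a moved list was shifted by 1. These counts therefore check the computation only, and do not cover lists whose genes vary together.

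Cells were clustered with the Leiden method at resolution 1 on 15 nearest neighbours in 15 principal components of the 2000 most variable genes, without batch correction. Alternatives fixed in advance were pseudocounts of 0.1 and 10, all cells, cells with at least 2000 genes, rescaling each cell to 1000000, the log2 ratio of mean RPKM, cells matched on genes detected, other filters on low values, other limits of detection and markers, and other cluster settings. Chosen after seeing the data were leaving out each stretch of sample numbers, leaving out cluster 6, using all columns without averaging, and clustering without genes that differ. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, scanpy 1.11.5, leidenalg 0.10.2 and matplotlib 3.10.9.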

Results

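The data are RPKM values of single macrophages from the aortic arch of mice, measured to compare atherosclerotic plaque before and shortly after its regression was set off by surgery. Donor mice lacked Apoe, the gene of apolipoprotein E, which clears remnant lipoproteins from blood, and ate a high-fat diet for 16 weeks; their arch cells form the baseline group. In the regression group, diseased arches were grafted into wild-type mice on chow and taken out 3 days later. Cells that carried CD45, CD11b and F4/80 were sorted and captured one by one on a microfluidic chip, and each library holds 1 cell. The 244 libraries came to 241 cells, because 3 pairs of baseline libraries (numbers 57 and 58, 64 and 65, 70 and 71) were near copies of each other and were averaged. Their log2 values correlated at 0.992 to 0.997, against at most 0.654 for any other pair of libraries. In whole reads they differed by more than Poisson noise (chi-square per degree of freedom 2.95 to 3.67), but far less than other neighbouring libraries (189.9 or more). After 3 regression cells with fewer than 1000 genes at RPKM of 1 or more were left out, 125 baseline and 113 regression cells remained.

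The median cell listed 2491 genes at RPKM of 1 or more at baseline (125 cells) and 2333 in regression (116 cells, including the 3 left out). Depth, estimated from the step that 1 read makes in low values, had a median of 1.09 M reads in 104 baseline libraries and 0.93 M reads in 78 regression libraries where 2 separate sets of genes gave the same step within 10%. Over the same 125 baseline and 116 regression cells, ribosomal protein genes held a median of 8.68% and 12.4% of summed RPKM. Mitochondrial genes held 7.09% and 8.08%. The labels name no animal, so each group counts as 1 sample, differences have no replicate check, and no p-value is given. The SDs below are spreads over cells. The intervals of shares are exact 95% binomial intervals that cover counting error only. Sample numbers fall into 5 stretches of consecutive numbers with 1 condition each (regression 1 to 20, baseline 21 to 92, regression 93 to 111, baseline 112 to 167, regression 168 to 244). Whether a stretch was a capture run is not given in the sources used here. Each stretch holds 1 group only, so no difference between the groups can be had within a stretch. Directions were therefore also read in the 6 pairings of a regression stretch with a baseline stretch.

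The first comparison checked the labels through the gene that donors lacked. Apoe (gene 11816, chromosome 7, 19696109 to 19699188, minus strand, mm10) was near the floor at baseline and among the most abundant transcripts in regression. Its mean log2(RPKM + 1) was 0.30 ± 1.11 (SD over 125 cells) at baseline and 11.86 ± 2.81 (SD over 113 cells) in regression, a difference of 11.56. RPKM of 1 or more was listed in 9 of 125 baseline cells (7.20%, interval 3.34 to 13.2%) and 112 of 113 regression cells (99.1%, interval 95.2 to 100.0%). Of the regression cells, 106 lay above the highest baseline cell, which stood at 7.49, and 7 lay at or below it. The difference was positive in 6 of 6 stretch pairings, from 8.45 to 12.42. Apoe thus separates the groups as labelled, but it does not mark regression cells as donor cells, since donors lacked the gene. Whether these cells came from the wild-type mice that received the grafts is left open below. The groups also differed in the host's Apoe genotype, its diet and the graft surgery, which cannot be told apart here.

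**Figure D1:**
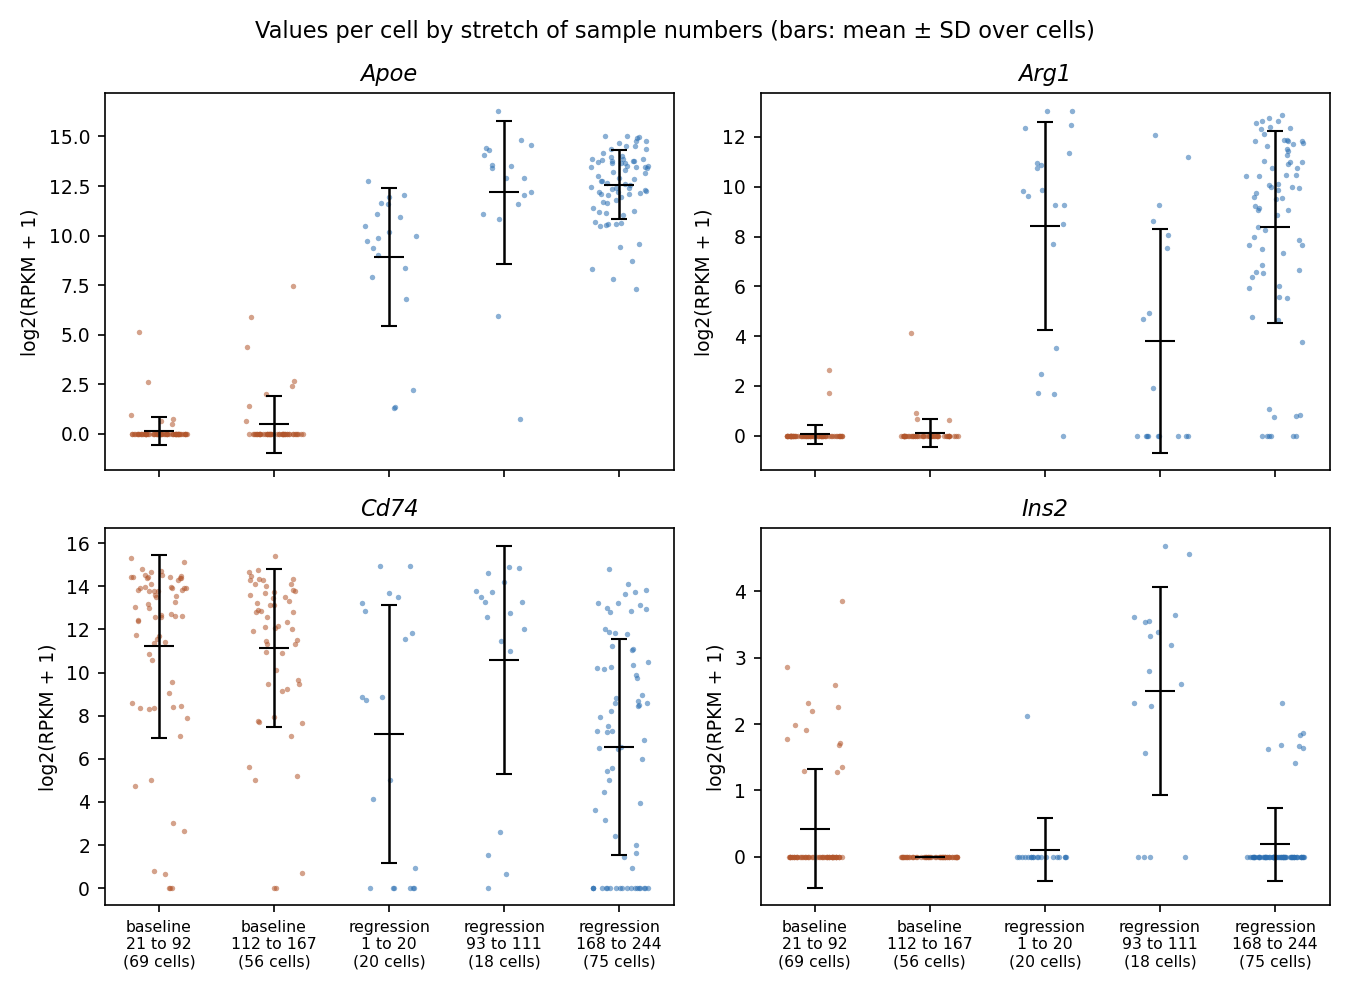
Log2(RPKM + 1) of 4 genes in each cell (points; vertical axes) by stretch of sample numbers (horizontal axis), baseline in brown and regression in blue, with the mean ± SD over cells in black. Apoe and Arg1 were higher in each regression stretch than in both baseline stretches; in cells 93 to 111, the Arg1 mean was 3.80, against 8.42 and 8.37 in the other regression stretches.

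The second comparison asked which genes differed most between baseline and regression cells, which also differ in Apoe as given above. Besides Apoe, the genes with the highest differences in regression were led by Arg1, an enzyme that splits arginine, Thbs1 and Fn1, which encode the matrix glycoproteins thrombospondin 1 and fibronectin, and Saa3, an acute-phase protein. Arg1 (gene 11846, chromosome 10, 24915221 to 24927484) had a mean of 0.09 ± 0.47 at baseline and 7.65 ± 4.32 in regression. It was listed in 2.40% of baseline cells (interval 0.50 to 6.85%) and 83.2% of regression cells (interval 75.0 to 89.6%). Thbs1 was higher in regression by 7.22, with 15.2% of baseline and 96.5% of regression cells, and Fn1 by 5.32, with 51.2% and 94.7% of cells. Saa3 differed by 4.94 and was listed in 4.80% of baseline and 49.6% of regression cells. Apoc2, an activator of lipoprotein lipase, differed by 4.34 (12.0% and 61.9% of cells). Hif1a, a transcription factor subunit of the hypoxia response, and Hilpda, a lipid droplet protein induced by hypoxia, both differed by 3.56. The C-type lectin receptor Clec4d (4.59), the lysosomal protease Ctsl (3.48), the phosphodiesterase Smpdl3a (3.20) and the chemokine receptor Ccr1 (3.15) complete the 12. All 12 had the higher mean in regression in 6 of 6 stretch pairings. The pairings reuse the cells on which these genes were picked for size, so for them they are a description and no separate check.

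The genes with the lowest differences in regression were led by the tetraspanin Cd81 and the lectin-like receptor Cd72. Cd81 (gene 12520) had a mean of 7.56 ± 3.23 at baseline and 1.83 ± 3.13 in regression, a difference of -5.73, and was listed in 88.8% (interval 81.9 to 93.7%) and 29.2% (interval 21.0 to 38.5%) of cells. Cd72 differed by -5.06, with 79.2% of baseline and 24.8% of regression cells. Abcg1, which exports cholesterol, differed by -4.52 (92.0% and 49.6% of cells), and the growth factor gene Igf1 by -4.50 (74.4% and 15.0% of cells). Slamf9 (-4.38), the chemokine Ccl4 (-4.05), the surface protein Cd83 (-3.98), the membrane protein Pmp22 (-3.92), the interferon-inducible Ifi27l2a (-3.75) and Herpud1, a protein of the endoplasmic reticulum stress response (-3.42), followed. Cd74, the invariant chain of MHC class II, differed by -3.87 and the class II chain gene H2-Aa by -3.61. Of these 12 genes, 11 had the lower mean in regression in 6 of 6 stretch pairings. H2-Aa had it in 4 of 6, because regression cells 93 to 111 had a mean of 10.24, above both baseline stretches. Without cells 168 to 244, differences moved by over 1.5 times for Saa3 (3.08), Cd74 (-2.39) and H2-Aa (-1.66). Under the log2 ratio of mean RPKM, which gives weight to the highest cells, the same rule named 9 of the 24 genes again.

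**Figure D2:**
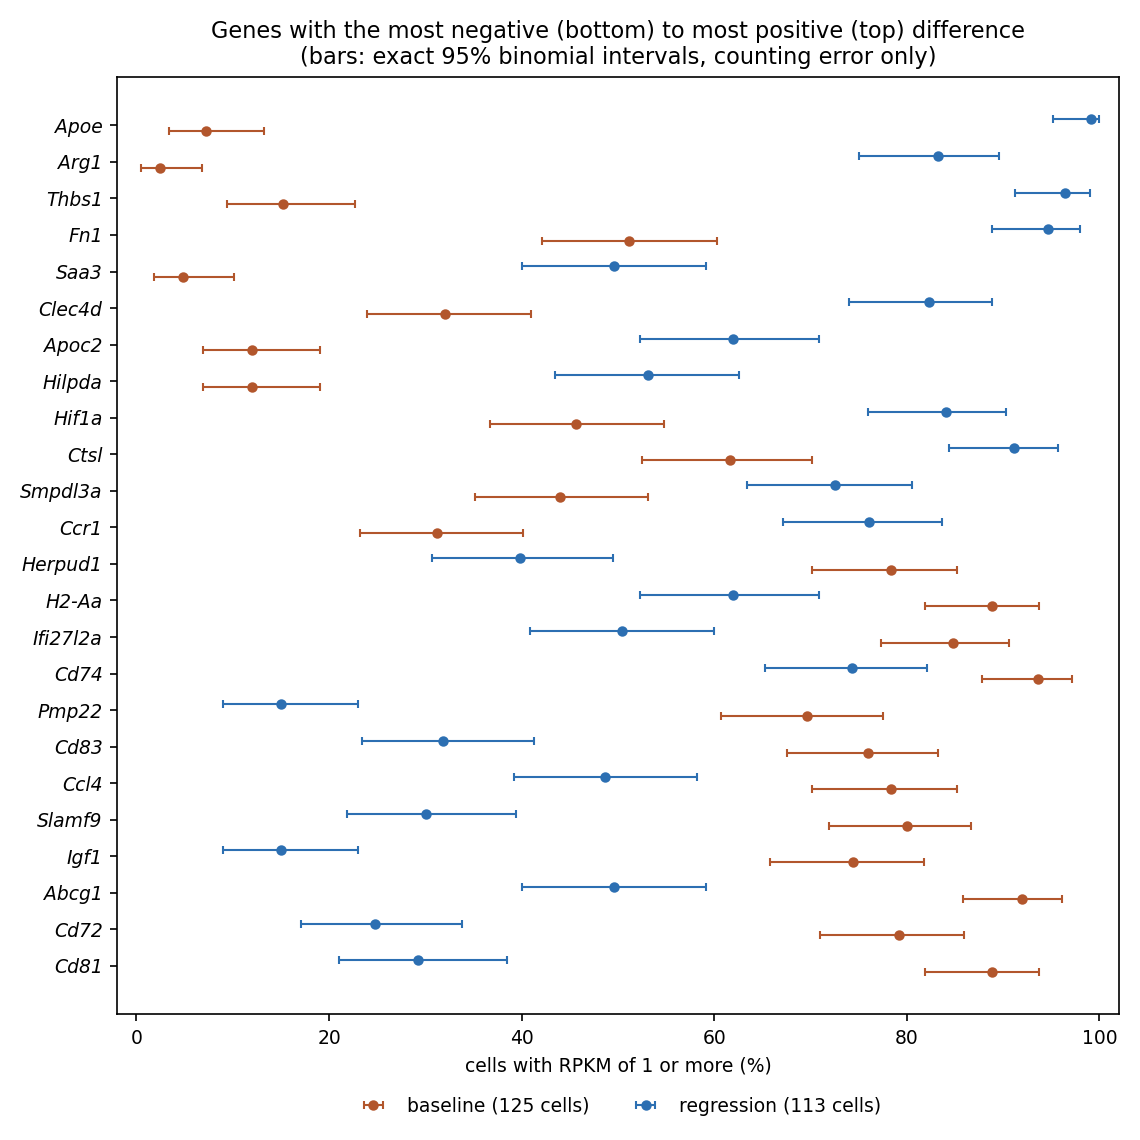
Percentage of cells with RPKM of 1 or more (horizontal axis) for the 12 genes with the most positive and the 12 with the most negative difference (vertical axis), in 125 baseline cells (brown) and 113 regression cells (blue), with exact 95% binomial intervals. Arg1 was listed in 2.40% of baseline and 83.2% of regression cells, and Igf1 in 74.4% and 15.0%.

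The third comparison took 20 gene lists fixed before the data were examined and placed each list's median difference among 10000 random lists matched on level, as a description of these libraries. Genes of antigen presentation by MHC class II had a median of -1.81, below every random list drawn (percentile 0.0), and 9 of 12 members had the lower mean in regression. H2-Ab1 differed by -2.96, H2-Eb1 by -3.40 and the costimulatory Cd86 by -2.62, while Cd80, Cd40 and Ctss lay between 0.17 and 0.29. The list's median was positive in 1 of the 6 stretch pairings (0.20). It was -0.75 without cells 168 to 244, -1.15 without cells 21 to 92 and -0.79 under the log2 ratio of mean RPKM. Interferon response genes had a median of -0.58 (percentile 0.0), with the lower mean in regression in 15 of 15 members, led by Rtp4 (-1.11) and Mx1 (-0.78). Only 3 of them were listed in at least 25% of the cells of a group, and their median (-0.61) lay inside the range of random lists. The median of the whole list was -0.34 without cells 112 to 167 and -1.79 under the log2 ratio of mean RPKM. Genes of lipid-laden macrophages had a median of -0.38 (percentile 0.75), with 11 of 15 members lower in regression. Among them, Cd9 differed by -2.60, the lipase Lpl by -2.38 and the elastase Mmp12 by -1.82, whereas Spp1 (1.03), Fabp5 (0.96) and the lipid droplet gene Plin2 (0.82) were higher. The list's median was -0.84 without cells 168 to 244 and -0.57 with genes in at least 25% of cells. Proliferation genes had a median of -0.27 (percentile 0.28), with 10 of 13 lower in regression, led by Stmn1 (-0.58). In 4 of 16 other settings, the proliferation median lay inside the central 95% of random lists, as at percentile 9.17 under the log2 ratio of mean RPKM (median -0.45).

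Glycolysis and hypoxia genes had a median of 1.33, above every random list drawn (percentile 100.0), and 13 of 14 members had the higher mean in regression. Hif1a differed by 3.56, the glycolytic enzyme Pgk1 by 2.67, the growth factor Vegfa by 2.65 and Ldha by 2.01, while Eno1 differed by -0.23. The monocyte list had a median of 1.57 (percentile 100.0), with 10 of 13 higher in regression. It was led by Thbs1 and Fn1, which other cells also make; Ccr2, the receptor that brings monocytes out of the bone marrow, differed by 2.03, but Ly6c2, a surface marker of classical monocytes, by -0.32. The list's median was 1.04 without cells 1 to 20. Matrix proteases and their inhibitors had a median of 0.43 (percentile 99.8), with 7 of 9 higher in regression, among them the membrane protease Mmp14 (1.49) and Adam8 (1.27). With no filter on low values, this median was 0.012, inside the range of random lists, as it was in 3 of 16 other settings in all (0.18 without cells 168 to 244). Under the log2 ratio of mean RPKM it was 1.22. Genes of the dissociation stress list, which includes immediate early genes that digestion of tissue can induce, had a median of -0.88 (percentile 0.03), with 10 of 14 lower in regression. Btg2 differed by -2.77 and Ier3 by 2.66. This median was -0.061, inside the range of random lists, without baseline cells 21 to 92, and -1.56 without baseline cells 112 to 167; under the log2 ratio of mean RPKM it was -0.58. With a pseudocount of 10, which shrinks the differences of low genes, medians were -0.19 for lipid-laden macrophages, -0.33 for interferon response, -0.14 for proliferation, -1.13 for MHC class II, 0.18 for proteases and -0.48 for dissociation stress. Ribosomal protein genes, taken as a measure of library quality, had a median of 0.52, above every random list drawn (percentile 100.0), with 82 of 96 higher in regression. The median of 16 mitochondrial genes was 0.35 (percentile 84.8).

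The other 12 lists lay inside the central 95% of random lists, several with members that went both ways. In other settings, 5 of them also lay outside: efferocytosis in 5 of 16 (as at percentile 0.13 in cells with at least 2000 genes), inflammatory in 3 (as at percentile 0.21 under the log2 ratio of mean RPKM), and alternative activation (percentile 99.94 with genes in at least 25% of cells), cholesterol efflux and resident macrophage genes in 1 each. In the alternative activation list (median -0.20, percentile 12.3), Arg1, the chitinase-like Chil3 (1.75) and Ccl24 (1.28) were higher in regression, and Mgl2 (-3.23) and Retnla (-2.74) lower. In the inflammatory list (-0.066, percentile 41.5), Cxcl2 (1.12) was higher and Ccl4, Ccl2 (-1.62) and Tnf (-1.50) lower. The cholesterol efflux list (0.20, percentile 94.4) held Apoc2 at one end and Abcg1 at the other, with the exporter Abca1 at 0.53. In the lysosome list (0.10, percentile 59.5), 8 of 15 members had the higher mean in regression, among them Ctsl, Lamp1 (2.70) and Ctsd (2.10), and 7 the lower. Among resident macrophage genes (-0.23, percentile 10.7), the platelet factor gene Pf4 differed by 3.09 and Igf1 by -4.50. Efferocytosis genes had a median of -0.27 (percentile 8.42), led by the receptors Axl (-2.11) and Havcr2 (-1.25). Medians were -0.25 for Wnt and beta-catenin genes (percentile 4.99), led by Ccnd1 (-1.93) and Myc (-0.39), and 0.20 for emigration genes (87.9), with Cx3cr1 at -0.92 and Cxcr4 at -0.77. The iron and oxidative stress list stood at 0.13 (85.2; Prdx1 -0.78, Sod2 0.73). Oxidative phosphorylation stood at 0.0068 (59.2; Cox5a 1.48, Uqcrc1 -1.46). Cholesterol synthesis stood at -0.011 (57.1; Cyp51 0.38), and retention, with 2 measured genes, at -0.013 (49.7; Cdh1 -0.15, Plxnd1 0.13). The median of the log2 ratios of mean RPKM had the opposite sign for alternative activation (0.27), cholesterol efflux (-0.011), cholesterol synthesis (0.32), resident macrophage (0.18), emigration (-0.24) and lysosome genes (-0.15). Over all settings, the sign stayed that given above in 5 of 16 for cholesterol synthesis, 9 of 16 for lysosome, 10 of 16 for oxidative phosphorylation, 12 of 15 for retention, 13 of 16 for alternative activation and for iron, and 14 of 16 for cholesterol efflux and for Wnt genes. Without cells 168 to 244, medians were -0.58 for lysosome (percentile 3.70), -0.22 for iron and 0.082 for alternative activation genes.

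**Figure D3:**
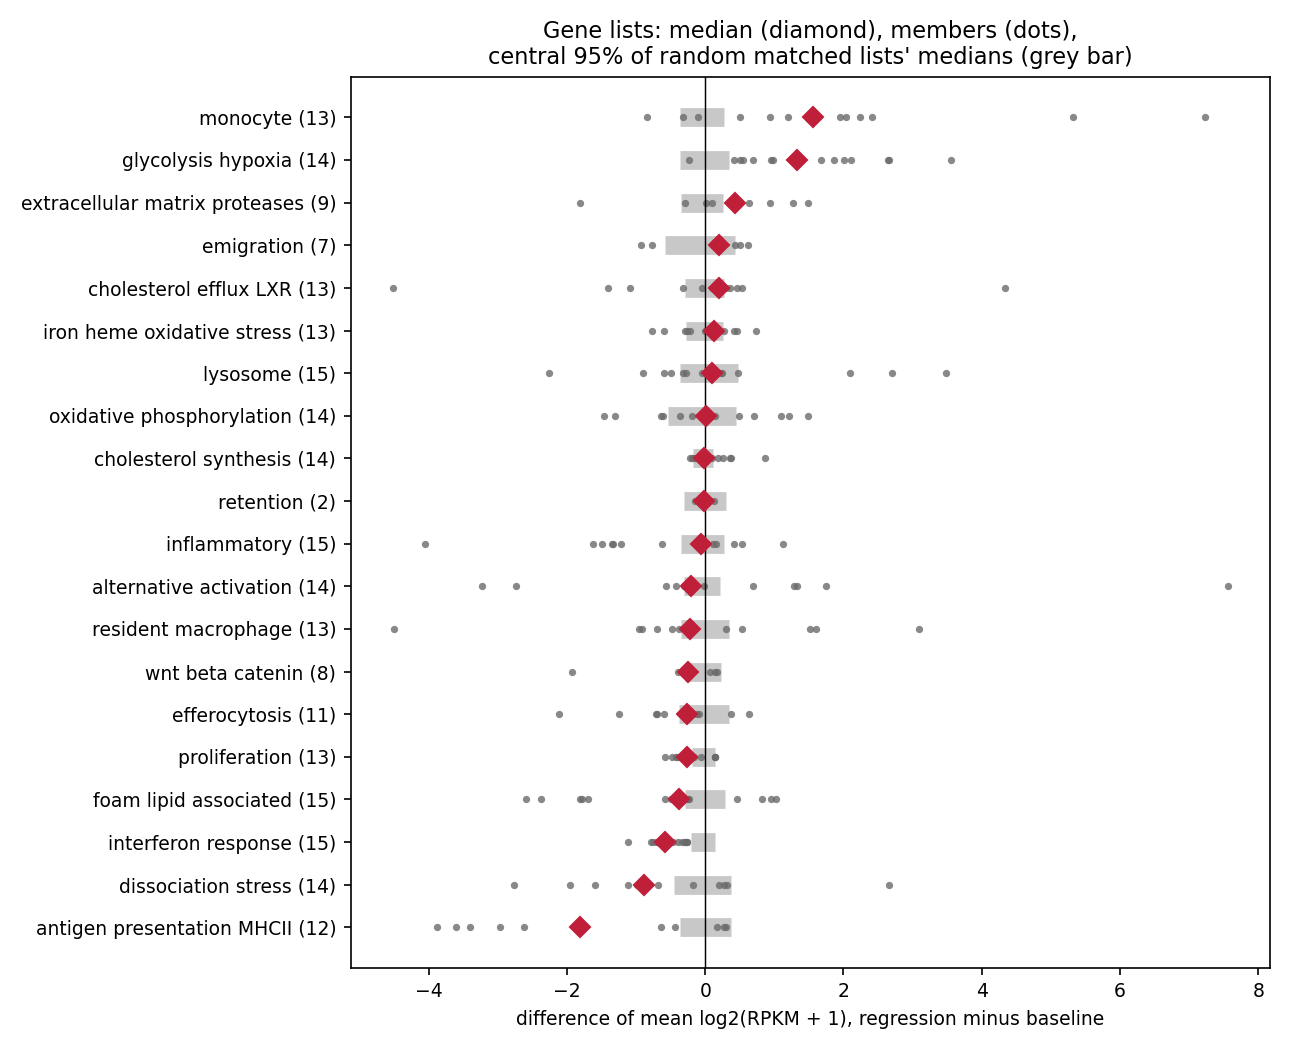
Difference of mean log2(RPKM + 1), regression minus baseline (horizontal axis), for 20 gene lists (vertical axis, measured members in brackets): diamonds are medians, dots are members and grey bars hold the central 95% of medians of random matched lists. Glycolysis and hypoxia genes (median 1.33) and MHC class II genes (median -1.81) lay outside their bars on opposite sides.

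Genes fixed for their role in plaque macrophages gave mixed values. Ccr7, a chemokine receptor that guides cells to lymph nodes, was listed in 4 of 125 baseline cells (3.20%, interval 0.88 to 7.99%) and in 0 of 113 regression cells, which allows a share of up to 2.65%. All 4 were among baseline cells 21 to 92. Itgam, which encodes the sorted antigen CD11b, was higher in regression by 1.64, Adgre1, which encodes F4/80, differed by -1.19 and Ptprc, which encodes CD45, by -0.70. Smaller differences were found for Il1b (0.53), Trem2 (-0.57), Mrc1 (-0.23) and Mki67 (-0.19). The log2 ratio of mean RPKM of Mrc1 had the opposite sign (0.16). Stretch pairings went both ways for Il1b, Trem2, Mrc1, Mki67, Ptprc and Abca1. Among the list genes taken by the rule, they did so for Rtp4, Stmn1, Mmp14, Btg2, Cox5a, Prdx1, Sod2 and Plxnd1. List members named only as examples, such as H2-Ab1 and H2-Eb1, were not read singly in the pairings or with a stretch left out. Without cells 168 to 244, differences that moved by over 1.5 times or changed sign were Pf4 (1.58), Btg2 (-1.30), Rtp4 (-0.56), Mmp14 (0.98), Cox5a (0.54), Cyp51 (0.60), Cd9 (-3.92), Stmn1 (-1.55), Cx3cr1 (-1.47), Cxcr4 (-1.21), Adgre1 (-1.97), Trem2 (-1.54), Il1b (2.42), Mrc1 (-0.41), Abca1 (-0.06) and Plxnd1 (-0.03). Without other stretches, they were Il1b (-0.19 without cells 1 to 20), Mrc1 (0.23 without cells 21 to 92), Lpl (-1.52 without cells 112 to 167) and Prdx1 (-0.19 without cells 112 to 167), among others.

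The fourth comparison counted cells that listed at least 3 markers of a cell type. Macrophage markers were found in 97.6% of baseline and 99.1% of regression cells. Classical monocyte markers were found in 18 of 125 baseline cells (14.4%, interval 8.76 to 21.8%) and 37 of 113 regression cells (32.7%, interval 24.2 to 42.2%). Nonclassical monocyte markers went the other way, with 23 baseline cells (18.4%, interval 12.0 to 26.3%) and 3 regression cells (2.65%, interval 0.55 to 7.56%). With 2 markers in place of 3, shares at baseline and in regression were 35.2% and 59.3% for classical and 34.4% and 10.6% for nonclassical monocytes. Each of the 6 nonclassical markers had the lower mean in regression, with a median of -0.57. Of the 6 classical markers, 4 had the higher mean in regression and 2 the lower. Ly6c2 was among the latter, listed in 16.0% of baseline and 6.19% of regression cells. Neutrophil markers were found in 4.00% of baseline cells (interval 1.31 to 9.09%) and 13.3% of regression cells (interval 7.62 to 20.9%), and in 6 of the 18 regression cells 93 to 111. With RPKM of 10 or more as detected, the neutrophil share of regression cells was 4.42%. Conventional dendritic cell markers were found in 4 baseline cells and no regression cell, and fibroblast markers in 2 and none. Markers of pancreatic islet cells were found in 2 regression cells, both among cells 93 to 111, and those of NK cells and of erythroid cells in 1 regression cell each. No cell listed 3 markers of eosinophils, T cells, B cells, mast cells, smooth muscle, endothelium or adipocytes, which allows up to 2.40% of baseline and 2.65% of regression cells. At least 4 proliferation genes at RPKM of 10 or more were found in 10.4% of baseline cells (interval 5.65 to 17.1%) and 7.96% of regression cells (interval 3.71 to 14.6%), which overlap. All 9 such regression cells were among cells 168 to 244, with 0 of 20 and 0 of 18 in the other regression stretches.

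**Figure D4:**
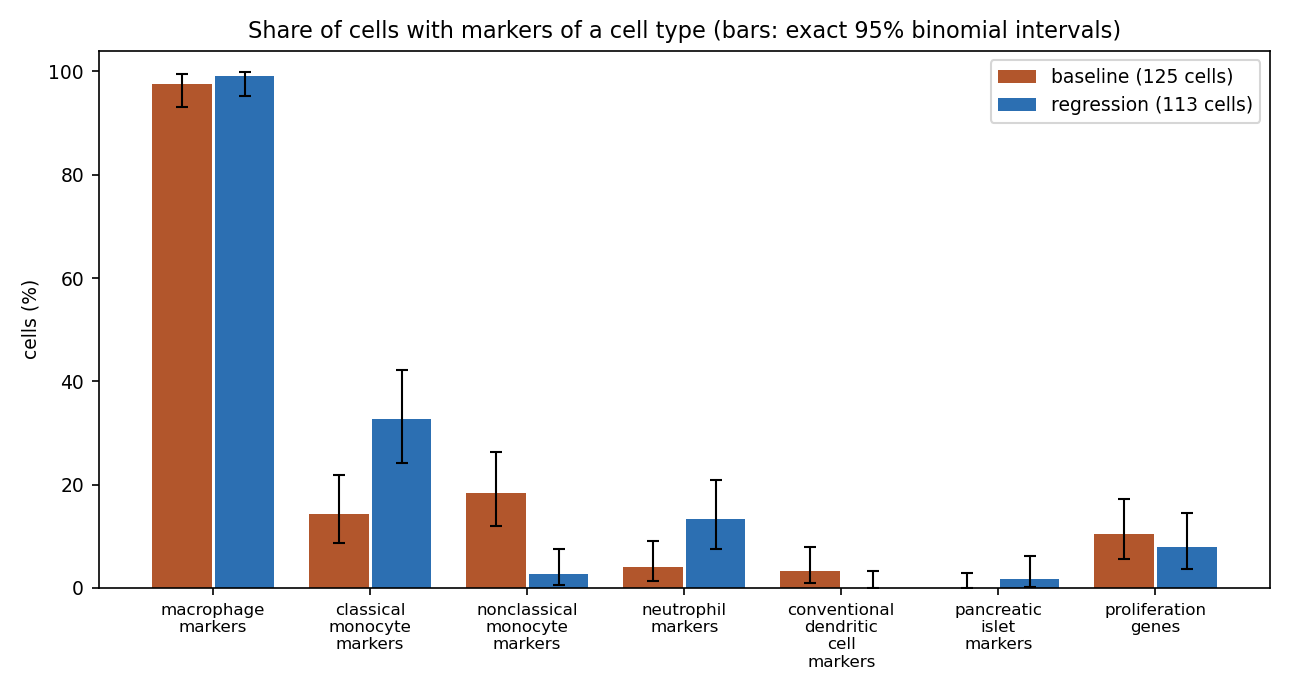
Percentage of cells (vertical axis) with at least 3 markers of a cell type, or at least 4 proliferation genes (horizontal axis), at baseline (brown) and in regression (blue); lines are exact 95% binomial intervals. Classical monocyte markers were found in 14.4% of baseline and 32.7% of regression cells, and nonclassical markers in 18.4% and 2.65%. The intervals cover counting error over cells only. They are no test between the groups, because the labels name no animal.

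The last comparison asked whether cells formed separate classes. Clustering gave 6 clusters, and 68.5% of cells lay in clusters with at least 90% of their cells from 1 group; at resolution 0.5, which gave 3 clusters, this was 13.0%. All 6 clusters had 7 or 8 macrophage markers listed in at least 50% of their cells, and none had a macrophage marker among its 10 leading genes. Clusters 1 to 5 are called macrophage-like by this count alone, which every cluster passes. In clusters 3 and 4, macrophage markers differed from other cells by a mean of -0.76 and 0.019. Classical monocyte markers differed by 0.58 and 1.07 there, so the name does not set clusters 3 and 4 apart from monocytes. Clusters also differed in genes detected, with medians per cell of 2370, 3291, 1918.5, 3140, 2262 and 1715 in clusters 1 to 6. The split between clusters and their marker differences may thus follow the number of genes detected in part, which was not tested. Cluster 6 (24 cells) was left unnamed, because 2 markers of nonclassical and 1 of classical monocytes were among its leading genes. The leading genes of clusters 1 to 5 include some of those named above for their difference between the groups, such as Apoe and Arg1, so cluster sizes are not compared between groups.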

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

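The tests in this part were chosen after the Apoe values had been seen. The table holds rows for vector sequences that no comparison in the report uses. The row named Neo, a selection gene that many knockout alleles carry, was listed in 5 of 125 baseline cells (4.00%, exact interval 1.31 to 9.09%) and in 0 of 113 regression cells, which allows up to 2.65%. It stands out as a signal in unused rows above the limit that 0 regression cells set, but 4 of the 5 cells were among cells 112 to 167; without these, 1 of 69 baseline cells (1.45%) remained, under that limit. LacZ was listed in 1 baseline cell and no regression cell.

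The pattern it bears on is Apoe, listed in 112 of 113 regression cells although the grafted arches came from mice without the gene. Apoe was the 11th most abundant gene in the median regression cell, with quartiles at ranks 4 and 77, but no empty well gives a background level, so free Apoe RNA taken up with the cells stays open. A candidate explanation is that most sorted cells came from the wild-type recipient within the 3 days. Neo could have shown this, had it been missing in regression beyond counting error, but its limit of 2.65% lies inside the baseline interval, so the test leaves recipient origin open. A transcript made by donor cells from the disrupted allele is another candidate. Baseline cells, which came from the donors, had an Apoe mean of 0.30 and listed it in 9 of 125 cells. Such a transcript was thus near the floor before grafting and would have to rise after it. To test such a rise would need reads by position, which were not analysed here.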

How the results depend on the processing

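Settings that leave out a stretch of numbers or cluster 6, use columns without averaging, or cluster without differing genes were chosen after seeing the data; the others were set before. Across 14 settings, the 24 genes named for size kept their direction, Apoe among them. The rule asks for the same sign of the log2 ratio of mean RPKM, so that setting could not reverse them. The other settings reuse cells on which these genes were picked for size, so they are a description and no separate check. Of 8 lists outside the central 95% of random lists, 4 stayed outside in all 16 settings (MHC class II, monocyte, glycolysis, lipid-laden). The interferon list did so in 15 (not with the 25% filter, which left 3 genes), the stress list in 15 (not without cells 21 to 92), proteases in 13 and proliferation in 12, and all 8 kept their sign. Values below moved by more than the SD of random lists' medians, the SD over cells or the exact interval. Pseudocounts and filters change the scale or the members by construction; for the rest, the cause was not tested.

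With a pseudocount of 0.1, the Apoe difference was 14.55. List medians were then alternative activation -0.42, lipid-laden -0.61, efflux 0.40, resident -0.49, monocyte 2.07, interferon -0.86, proliferation -0.40, MHC class II -2.48, protease 0.75, efferocytosis -0.45, glycolysis 1.79 and stress -1.26. With a pseudocount of 10, the Apoe difference was 8.52. List medians were then alternative activation -0.052, lipid-laden -0.19, efflux 0.045, monocyte 1.08, interferon -0.33, proliferation -0.14, MHC class II -1.13, protease 0.18, glycolysis 0.97, stress -0.48 and Wnt -0.091.

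In cells with at least 2000 genes, medians were cholesterol synthesis 0.14, efferocytosis -0.50, lysosome 0.32, iron -0.075 and Wnt 0.10. Rescaling gave MHC class II -2.002, and matching on genes detected gave cholesterol synthesis 0.088. By the log2 ratio of mean RPKM, 9 of the 24 genes named were shared. The medians were alternative activation 0.27, inflammatory -0.61, lipid-laden -0.55, efflux -0.011, cholesterol synthesis 0.32, resident 0.18, interferon -1.79 and proliferation -0.45. The others were emigration -0.24, MHC class II -0.79, protease 1.22, efferocytosis -0.61, lysosome -0.15, oxidative phosphorylation 0.31 and stress -0.58. With no filter on low values, medians were monocyte 1.38, proliferation -0.18, protease 0.012, glycolysis 0.98 and Wnt -0.0097. With genes in at least 25% of cells, they were alternative activation 0.69, inflammatory -1.21, lipid-laden -0.57, efflux -0.040, cholesterol synthesis 0.36, monocyte 1.95, proliferation -0.48, MHC class II -2.62, protease 0.10 and glycolysis 1.68; no retention gene passed.

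Without cells 1 to 20, medians were inflammatory -0.45, cholesterol synthesis -0.11, monocyte 1.04 and MHC class II -2.08. Without cells 21 to 92, they were alternative activation -0.043, monocyte 1.23, interferon -0.84, MHC class II -1.15 and stress -0.061. Without cells 93 to 111, they were alternative activation -0.051, monocyte 1.86 and Wnt -0.088. Without cells 112 to 167, they were inflammatory -0.25, efflux 0.010, cholesterol synthesis 0.11, interferon -0.34, retention 0.15, MHC class II -2.10, stress -1.56 and Wnt 0.055. Without cells 168 to 244, they were alternative activation 0.082, inflammatory -0.36, lipid-laden -0.84, efflux 0.018, resident -0.48, monocyte 1.23 and interferon -0.42. Also in this setting, MHC class II was -0.75, protease 0.18, efferocytosis -0.95, lysosome -0.58, iron -0.22 and Wnt -0.45, and 73.7% of regression cells listed Arg1 and 0% had 4 proliferation genes. Without cluster 6, medians were inflammatory -0.37, MHC class II -2.18, lysosome -0.29, oxidative phosphorylation -0.25, iron -0.15 and Wnt -0.10.

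With RPKM of 10 or more as detected, classical monocyte markers were found in 8.00% of baseline and 21.2% of regression cells, nonclassical markers in 12.0% of baseline cells and neutrophil markers in 4.42% of regression cells. With at least 2 markers, shares at baseline and in regression were 35.2% and 59.3% for classical monocytes, 34.4% and 10.6% for nonclassical monocytes, 22.4% and 39.8% for neutrophils and 100% in both for macrophages. The macrophage share was also 100% at baseline without cells 21 to 92, and in regression without cells 93 to 111 or without cluster 6. At resolution 0.5, 3 clusters formed and 13.0% of cells lay in clusters with at least 90% from 1 group. With 30 components this was 79.4%, and without genes that differ by 1 or more between the groups 0%, a choice that removes such clusters by construction.

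Leaving out capture runs was not run, because column names show none. No paired analysis was possible because the groups share no sample number. Depth was estimated in 182 of 244 libraries only, and shares near 0 are limited by the number of cells.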

Other observations

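In this part, the tests on matched cells and on genes around Apoe were set before their results were seen, and the tests of labels and of islet markers, and the repeats of the matching, after. Among resident macrophage genes, Maf (1.60) and F13a1 (1.52) were higher in regression, while Lyve1, a receptor of resident macrophages in vessel walls, differed by -0.91 and was listed in 32.8% of baseline cells (interval 24.7 to 41.8%) and 9.73% of regression cells (interval 4.96 to 16.7%). Retnla was listed in 45.6% of baseline cells (interval 36.7 to 54.7%) and 5.31% of regression cells (interval 1.97 to 11.2%), and Chil3, another gene of the alternative activation list, in 15.2% and 37.2%. S100a8, which neutrophils and monocytes make, was listed in 8.80% and 23.9% of cells. The genes of this paragraph were chosen after their values were seen.

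Regression cells 93 to 111 stood apart from other regression cells. Their Arg1 mean was 3.80 ± 4.50 (SD over 18 cells), against 8.38 ± 3.90 in other regression cells, and their Cd74 mean was 10.60 ± 5.29, against 6.68 ± 5.20. Baseline cells under a regression label are argued against by Apoe, which lay above the highest baseline cell in 16 of the 18 (88.9%, interval 65.3 to 98.6%). Ins2 was listed in 14 of the 18 and also in 14 of 69 baseline cells 21 to 92 (20.3%, all numbered 72 to 91), 8 of 75 regression cells 168 to 244 and 1 of 20 regression cells 1 to 20. In the 18 cells, the 7 islet markers held a median of 0.000993% of summed RPKM, against 1.21% for Cd74. This argues against RNA of endocrine islet cells, which these markers mark, as the source of Cd74. Other cells of the islet are not covered by them. Fewer genes per cell (median 1893, against 2422) as the whole cause is argued against by regression cells matched on genes detected: Arg1 differed by -4.13 (-3.71 to -4.17 in 100 matchings, unmatched -4.58) and Cd74 by 3.86 (3.64 to 4.07, unmatched 3.92). With 18 cells a side, the intervals of the shares of cells with each gene overlapped, and a smaller part played by genes detected stays open. A difference between animals or capture runs stays open and was not tested.

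Apoc2 lies beside Apoe on chromosome 7 and differed by 4.34, so the engineered region may have affected nearby genes. The 25 measured genes within 1000000 bases of Apoe had a median absolute difference of 0.12, at percentile 4.09 among random lists matched on level, where a regional effect needs a high percentile. Of these genes, Pglyrp1 (-1.61) and Vasp (0.96) differed most after Apoc2. Apoc1, Apoc4 and Tomm40, the closest neighbours besides Apoc2, lay near the floor in both groups and argue neither way. Most of the 25 genes likewise had means below 1 in both groups. A median over them could hardly show a regional effect, so the percentile does not decide on one. An effect on single genes, such as Apoc2, was not tested.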
